A study of Mus musculus with 10 samples.

How the data were processed

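Total RNA was extracted with TRIzol from 10 single-cell-derived lines of mouse small cell lung cancer grown in RPMI1640 with serum, amplified, labelled with the dye Cy3 and hybridised to Agilent mouse expression arrays with 1 colour, per the labels' protocols. The deposited scanner files give intensity values that Agilent Feature Extraction 10.7 made from the scans, per the submitters' processing notes (version 10.7.3.1 per the file headers). These processed intensities are background-subtracted and detrended within the array, with no scaling between arrays, per the file headers. Each file also gives the raw median intensity of spot and local background. The authors also deposited 2 tables of log2 values, which the series text says were quantile-normalized in GeneSpring 11.0. Both tables held the same values (largest difference 0), each column had a median of 5.07, and each correlated with its own array's log2 scanner values at 0.9996 to 0.9999 across probes, so their scale is log2, uncentred and of the same direction. The series text names gene set enrichment analysis without the gene sets, and that analysis was not repeated.

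The samples were grouped by their titles as 5 Mes and 5 Epi lines, and the single comparison was Mes minus Epi. Of 43379 spots that were not controls (1639 control spots were left out), 46 to 87 per array carried outlier flags and were left out, and spots of 1 probe were averaged, giving 41174 probes. The median coefficient of variation of replicate spots was 4.11% to 5.45% per array. Probes were named from the authors' deposited table of log2 values, which gave a gene for 34893, and symbols were updated through a RefSeq table of GRCm38.p6 matched by Entrez ID for 33405 (3415 symbols changed, 1488 kept as in the file). The other 6281 probes had no name. Coordinates are those of the deposited table, on mm9.

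The main values were log2 of quantile-normalized processed intensity, with a floor of 1, as the series text names quantile normalization. A probe was tested when it was well above background on all 5 arrays of at least 1 group (24475 probes), and a gene was represented by its brightest tested probe (13202 genes). Of 5974 genes with over 1 tested probe, 36 had probes called in both directions. Models were fitted with lmFit and eBayes in limma 3.58.1 (R 4.3.3), with Benjamini-Hochberg adjustment over the tested probes and a threshold of 0.05. Gene lists were tested with limma's camera with a preset correlation of 0.01, adjusted over the 27 lists with at least 5 measured genes, and counts adjusted over the list alone were given beside those over all tests. The scores per line, and the list means per line with adjustment over the 27 lists, were compared by an exact two-sided permutation test over 252 assignments. A gene was called off in a group when none of its probes was well above background on any array there. For such a gene, or where some arrays of the dim group were not above background, the fold is a bound, the bright group's mean against the dim group's mean of, per array, the higher of the lowest signal above background and the probe's own. List medians were also taken with such genes at their bounds, and none of the 27 changed. The fold is no strict bound for Cdh1 and Krt8, where some arrays of the bright group were also not above background.

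The named genes were fixed by a rule before the data were examined. It took 22 single genes, the 10 largest differences per direction among genes measured on all arrays whose groups do not overlap, the 5 largest bounds per direction and up to 4 differing members of each list, or up to 2 members where none differed, leaving out names that are only identifiers in the sets of largest differences and bounds. Some genes that the rule took are not reported here, while all counts include them. The lists covered epithelial adhesion, keratins, desmosomes, mesenchymal genes, transcription factors of the epithelial to mesenchymal transition, collagens, matrix remodelling, TGF-beta, YAP and TAZ, neuroendocrine genes, Notch, tuft cells, lung cell types, cell cycle, MYC, RB and p53, interferon, antigen presentation, cytokines, receptor tyrosine kinases, Wnt, integrins, glycolysis, cholesterol synthesis, immediate early genes, endothelium and leukocytes. Erythroid and muscle genes and sex-linked genes were listed but had too few measured genes or were checks of origin.

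Alternatives set in advance covered 75th percentile scaling, normexp background correction with an offset of 50, both deposited log2 tables, no filter on dim probes, probes above background on all 10 arrays, slide as a fixed or random block (statmod 1.5.0), slide 2 alone, the replicate number as a block, array weights, a trended robust fit, a floor of 16, a mean over the probes of a gene, each array left out, an estimated correlation, fry and fgsea 1.28.0. The mean-signal column was missing from the files, so normexp used the median spot and background intensities. Removing chromosomes 4, 9 and 10 and removing slide 2 were added after the data were seen. Of 12 tests of explanations, 4 were written before and 8 after the values were seen. Tests by symbol family and by chromosome were also chosen after. The fit was tested on simulated data built on the Mes against Epi comparison with 13191 genes, where it recovered 57% of genes changed by 1 and 89% of those changed by 2 on the log2 scale, and 3.95% of its calls were unchanged genes. The simulation changed 200 genes and drew independent noise per gene and array, without slide effects or lines more alike than others. Its share of false calls therefore does not carry over to the real comparison.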

Results

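Messenger RNA was measured in 10 lines of mouse small cell lung cancer cells, each grown from a single cell of a tumour labelled as lacking the neuroendocrine state, in which such tumours make hormone and nerve cell proteins. The labels place 5 lines in a group named Mes and 5 in a group named Epi and do not spell these names out. Every line carries the genotype label RbL/L, Trp53L/L, the usual notation for loxP-flanked alleles of both tumour suppressor genes. The cells received no treatment. Each line was hybridised to 1 array, and between 24871 and 26515 of the 41174 probes (60.4% to 64.4%) were well above background on an array. No spot was saturated. The labels do not say whether the lines came from separate tumours, so the p-values measure only the spread between these lines, and 5 arrays per group limit the precision of every value.

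The comparison asked which genes differ between the Mes and Epi lines. Rb1 signal was 7.01 ± 0.30 in Mes and 7.18 ± 0.42 in Epi lines (log2, SD, n = 5 each), with an adjusted p of 0.61, and Trp53 signal was 9.39 ± 0.22 and 9.12 ± 0.15, with an adjusted p of 0.18. Neither probe is known to lie in a deleted part of its gene, so these values check nothing about the genotype. All differences below are Mes minus Epi on the log2 scale, from limma.

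The Mes and Epi lines differed in 3752 of 13202 measured genes (28.4%), of which 2070 were higher and 1682 lower in Mes lines. At least 2-fold differences were found for 1749 genes, 886 higher and 863 lower. Collagen I, Sfrp1, Wnt10a and Krt7 were among the genes higher in Epi lines, and Psmb8, Wnt5a, Notch3 and Efnb1 among those higher in Mes lines. For 2499 genes (18.9%) no Mes value overlapped any Epi value, against 0.794% by chance for 5 against 5. By probe, 6770 of 24475 differed. Correlations across probes, which are not independent replicates, ran from 0.903 to 0.939 between the groups, 0.948 to 0.986 among Mes and 0.959 to 0.984 among Epi arrays. Mes2 and Mes3 correlated at 0.986, against at most 0.969 for the other Mes pairs. Epi3, Epi4 and Epi5 correlated with each other at 0.981 to 0.984, against at most 0.969 for the other Epi pairs. The lines of a group were thus not equally distinct, and p-values that count them as 5 independent lines may be too small.

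Slides and groups overlapped only on slide 2, which held Mes3, Mes4 and Epi2. Slide 1 held the other Epi arrays and slide 3 the other Mes arrays. With slide as a fixed block, 97 genes and 179 probes differed. Within slide 2 alone, where the lone Epi array was assumed to vary like the Mes arrays, limma called 0 genes and 0 probes, and 2290 genes had an unadjusted p under 0.05. With 1 Epi array, values within slide 2 and with slide as a fixed block compare Epi2 alone with Mes lines and cannot show a difference between the groups. Many genes on chromosomes 4 and 9 were higher and on chromosome 10 lower in Mes lines, and without these chromosomes 2388 genes differed. Of the differing genes named here or among the further observations, Ccnb2, Cep57, Col5a3, Cryab, Gsta4, Ncam1, Shfl, Slco2a1 and Tmod2 lie on chromosome 9, Dlgap3, E2f2, Sesn2, Tgfbr1 and Tox on chromosome 4, and Egr2, Hk1, Igf1, Itga7 and Pfkl on chromosome 10.

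Of 27 gene lists fixed before the data were examined, 3 were shifted upward and 1 downward in Mes lines by limma's camera test. None of the 27 passed with an estimated correlation between genes, where the lowest adjusted p was 0.377. Of 100 splits of the arrays, the real one included, 54 gave at least 4 lists, so the list calls rest on little. The ranges of adjusted p over alternatives given below leave out fry, which tests another question. Within slide 2, 22 of the 27 medians kept their sign, and those of transcription factors of the epithelial to mesenchymal transition (0.34), YAP and TAZ (0.10), cholesterol synthesis (0.25), immediate early genes (-0.30) and endothelium (-2.30) turned.

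The antigen presentation list was shifted upward in Mes lines. Of 14 measured, 8 were higher and 1 was lower, or 9 and 1 adjusted over the list alone. Psmb8, a subunit of the immunoproteasome that cuts proteins into peptides for display, was 12.09 ± 0.94 in Mes and 7.59 ± 0.41 in Epi lines, a difference of 4.50 (SE 0.41, adjusted p = 0.000168). H2-K1, a class I molecule that presents peptides to T cells, rose by 3.03 (SE 0.60, adjusted p = 0.0056). Cd74, the invariant chain of class II molecules, was the member that was lower, by -2.09 (adjusted p = 0.0295), a call that ended without Mes2, Mes3, Mes4, Epi4 or Epi5 (adjusted p of up to 0.0706) and with normexp, no filter on dim probes or a floor of 16 (up to 0.164). For this list the median was 1.11 (camera adjusted p = 0.00943), with adjusted p = 0.377 with an estimated correlation. The median was 0.67 with slide as a block (adjusted p = 0.0318) and within slide 2 (adjusted p = 0.048) and 0.56 with normexp background correction, and adjusted p over the alternatives ranged from 0.00108 to 0.377.

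The interferon response list was also shifted upward in Mes lines. Of 25 measured, 9 were higher and 0 lower, or 10 and 0 adjusted over the list alone. Ifih1, a sensor of double-stranded RNA, was at least 12.8-fold higher in Mes lines (adjusted p = 0.000525) and above background on 4 of 5 Epi arrays. Oasl2, of the oligoadenylate synthetase family, was at least 12.6-fold higher (adjusted p = 0.00567) and Oasl1 at least 9.45-fold (adjusted p = 0.00708), with 4 and 2 of the Epi arrays above background. Shfl, an interferon-induced inhibitor of viral translation and no member of the list, rose by 5.30 (SE 0.78, adjusted p = 0.00146). The list median was 1.01 (camera adjusted p = 0.0102), with adjusted p = 0.618 with an estimated correlation. The call also ended with probes above background on all 10 arrays (adjusted p = 0.0535), with slide as a block (median 0.45, adjusted p = 0.19) and within slide 2 (0.45, adjusted p = 0.1), the normexp median was 0.50, and adjusted p over the alternatives ranged from 0.00166 to 0.618.

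**Figure D1:**
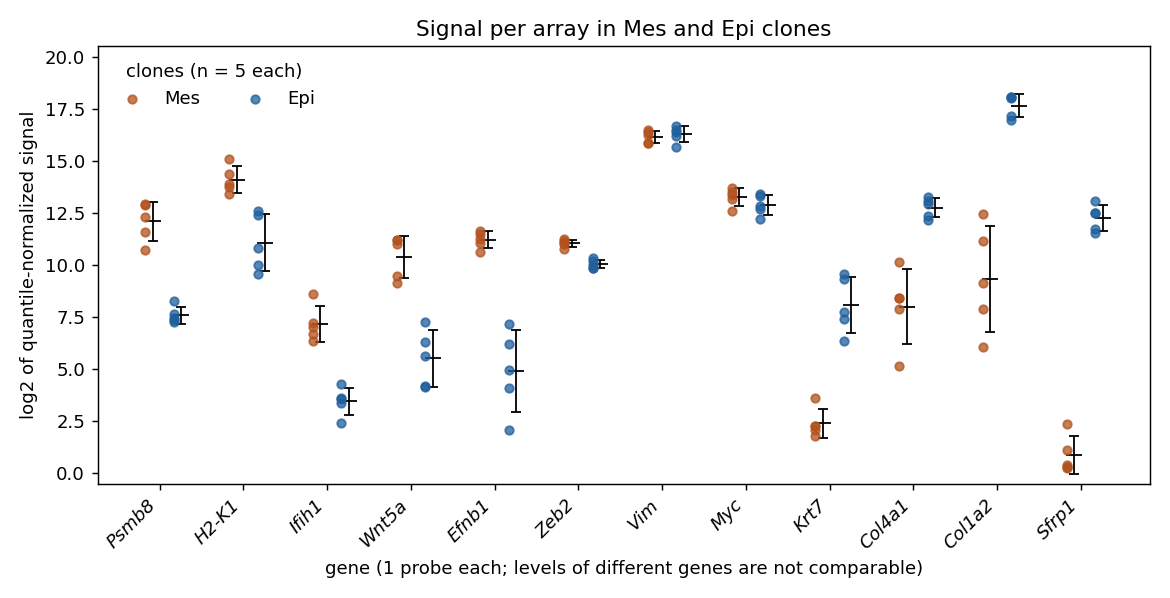
Log2 of quantile-normalized signal (vertical axis) of 12 genes, with a point per array, 5 Mes lines in orange and 5 Epi lines in blue, and black bars for the mean and SD. Psmb8 averaged 12.09 in Mes and 7.59 in Epi lines, Col1a2 averaged 9.33 and 17.65, and the Vim points of both groups overlap.

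The list of fibrillar and other collagens was shifted downward in Mes lines. Of 19 measured, 6 were lower and 1 was higher, with the same counts adjusted over the list alone. Col1a2, a chain of collagen I (probe on chromosome 6, 4490619 to 4490678 of mm9), was 9.33 ± 2.54 in Mes and 17.65 ± 0.56 in Epi lines, a difference of -8.31 (SE 1.02, adjusted p = 0.000648). Col1a1, the other chain of collagen I, differed by -7.41 (SE 1.22, adjusted p = 0.00234), and Col4a1, of basement membrane collagen IV, by -4.75 (SE 0.73, adjusted p = 0.00173). Col5a3, a chain of collagen V, was the member that was higher, by 4.37 (SE 0.62, adjusted p = 0.00126). The list median was -0.76 (camera adjusted p = 0.0183), with adjusted p = 0.377 with an estimated correlation. The median was -0.83 with slide as a block (adjusted p = 0.0425) and within slide 2 (adjusted p = 0.0115), it was -1.41 without chromosomes 4, 9 and 10, the call also ended with fgsea (adjusted p = 0.0818), and adjusted p over the alternatives ranged from 0.0038 to 0.377.

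Among 26 matrix remodelling genes, 9 were lower and 1 was higher in Mes lines, or 10 and 2 adjusted over the list alone. The list did not pass (median -0.58, camera adjusted p = 0.0571), but did without Mes1 (adjusted p = 0.0166) or Epi2 (0.0296), without the filter on dim probes (0.0393), with slide as a random block (0.0481), the replicate block (0.0306), array weights (0.0256) or fgsea (0.0433), and on slides 1 and 3 only (0.034). Its adjusted p over the alternatives ran from 0.0166 to 0.431.

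The cell cycle list was shifted slightly upward in Mes lines, a call that several settings ended. Of 38 measured, 9 were higher and 1 was lower, with the same counts adjusted over the list alone. Ccnb2, a cyclin of mitosis, rose by 1.44 (SE 0.17, adjusted p = 0.00049), and Cdc45, needed to start DNA replication, by 1.23 (SE 0.17, adjusted p = 0.00104). Aurkb, a kinase of chromosome segregation, rose by 0.96 (adjusted p = 0.0101). E2f2, a transcription factor of the S phase, rose by 1.65 (adjusted p = 0.0263), was -0.05 within slide 2, and lost its call without Mes5, Epi3, Epi4 or Epi5 (adjusted p of up to 0.0651) and without the filter on dim probes (0.0517). The median of the list was 0.30 (camera adjusted p = 0.0267), with adjusted p = 0.716 with an estimated correlation. The call also ended without Mes4 (adjusted p = 0.0692), Mes5 (0.0583), Epi4 (0.0697) or Epi5 (0.092), with 75th percentile scaling (median 0.15, adjusted p = 0.102), with slide as a block (median 0.08, adjusted p = 0.844) and within slide 2 (0.08, adjusted p = 0.838), and adjusted p over the alternatives ranged from 0.00342 to 0.844.

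Few genes of epithelial adhesion passed the filter on dim probes. Of 40, 22 were above background on at least 1 array, 5 were measured, and F11r, a tight junction adhesion molecule, was the single one that differed, higher in Mes lines by 3.54 (SE 0.88, adjusted p = 0.0148) and by 0.99 within slide 2. Cdh1, the E-cadherin of epithelial junctions, was above background on 3 of 5 Epi and 0 of 5 Mes arrays, with means of 3.62 ± 1.10 and 0.53 ± 0.17. Against the lowest signal above background on the Mes arrays, it was 2.49-fold higher in Epi lines. Krt8, a keratin of simple epithelia, was above background on 4 Epi and 0 Mes arrays, with means of 4.58 ± 1.68 and 0.93 ± 0.66. By the same measure it was 4.85-fold higher in Epi lines. For both genes the fold is no strict bound, since not all Epi arrays were above background. Others leaned to the Mes lines, with Spint1, a protease inhibitor of epithelia, above background on 3 Mes and 0 Epi arrays (3.14 against 0.24) and Esrp2, a splicing factor of epithelial cells, on 4 Mes and 2 Epi arrays (3.70 against 2.64). Every Epi line lay above every Mes line for Cdh1 and Krt8. Esrp2 overlapped between the groups, as did the brighter Spint1 probe, with 0.17 in Mes1 and 0.27 in Mes4. On the other Spint1 probe every Mes line lay above every Epi line, but only 2 Mes and 0 Epi arrays were above background there. Mes1 (0.98) and Mes4 (1.02) lay near the floor, as did the Epi lines, so this order means little. Cdh1, Krt8, Spint1 and Esrp2 did not pass the filter and were not tested. Epcam, an epithelial cell adhesion molecule, was not well above background on any array. The list median was 0.73 (camera adjusted p = 0.213), and 0.14 with slide as a block (adjusted p = 0.794) and within slide 2 (adjusted p = 0.741), 0.09 with normexp and -0.01 without the filter on dim probes, with adjusted p over alternatives from 0.13 to 0.861.

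Single keratin and adhesion genes were lower in Mes lines, while none of their lists passed camera. The exact permutation test of list means per line, which does not compare a list with other genes, gave another answer. Means were lower in Mes lines for keratins (-1.36, adjusted p = 0.0268), desmosomes (-1.19, 0.0268) and integrins (-0.97, 0.0358). By this test the mean of the epithelial adhesion list was higher in Mes lines (1.12, adjusted p = 0.0358). Means were also higher for antigen presentation (1.18), interferon (1.29) and Notch (0.65), each with adjusted p = 0.0268. They were lower for collagens (-1.83), matrix remodelling (-0.68) and receptor tyrosine kinases (-0.65, each 0.0268) and for tuft cells (-2.03) and leukocytes (-0.40, each 0.0358). The other lists did not pass this test, cell cycle among them (0.37, adjusted p = 0.0834). Krt7, a keratin of simple epithelia, was 2.40 ± 0.69 in Mes, where 1 of 5 arrays was above background, and 8.07 ± 1.35 in Epi lines, at least 43.9-fold higher in Epi lines (adjusted p = 0.000345). It was the only one of 8 measured keratins to differ (list median -0.68, camera adjusted p = 0.141), with the same count adjusted over the list alone. The keratin list had an adjusted p of 0.048 within slide 2 (median -0.95), which rests on Epi2 alone, and of 0.0916 with slide as a block, and its median was -0.09 with normexp, -1.67 without Epi5 and -0.22 without Mes2, with adjusted p over alternatives from 0.048 to 0.377. Itga6, the integrin of hemidesmosomes, was at least 35.1-fold higher in Epi lines (adjusted p = 0.00591) and above background on 3 of 5 Mes arrays. Of 11 desmosome and hemidesmosome genes, 2 were lower and 0 higher, with the same counts adjusted over the list alone (median -0.95, camera adjusted p = 0.141). Of 15 integrins, 3 were lower and 0 higher, or 2 and 0 adjusted over the list alone (median -0.52, camera adjusted p = 0.0571). The integrin list passed without Mes1 (adjusted p = 0.0224), Mes5 (0.0352) or Epi2 (0.0181), without the filter on dim probes (0.0409), with slide as a random block (0.0481), the replicate block (0.0306) or array weights (0.0256), and on slides 1 and 3 only (0.0352). Its adjusted p over the alternatives ran from 0.0181 to 0.377. Itga7, a laminin receptor, differed by -2.54 (SE 0.32, adjusted p = 0.000714).

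Some mesenchymal genes were abundant in both groups, while 7 of the 40 in the list were not above background on all Mes arrays. Vim, the intermediate filament of mesenchymal cells, was 16.16 ± 0.29 in Mes and 16.27 ± 0.39 in Epi lines (adjusted p = 0.728), and Fn1, the matrix protein fibronectin, was 12.01 ± 0.31 and 12.26 ± 0.28 (adjusted p = 0.359). Of 34 measured mesenchymal genes, 1 was higher and 5 were lower, or 1 and 3 adjusted over the list alone, and 28 did not pass. The higher one was Zeb2, a repressor of E-cadherin, by 0.98 (SE 0.14, adjusted p = 0.00148). Its relative Zeb1 was lower by -0.56 (adjusted p = 0.0355), a call that ended without Mes2, Mes3, Mes4, Epi1, Epi3 or Epi5 (adjusted p of up to 0.0799). Snai1, Snai2 and Twist1, transcription factors of the epithelial to mesenchymal transition, had adjusted p of 0.359, 0.519 (0.0484 without Mes1) and 0.573, and Cdh2, the N-cadherin, had 0.226. The list median was -0.18 (camera adjusted p = 0.213), and -0.13 with slide as a block (adjusted p = 0.944) and within slide 2 (adjusted p = 0.741), over alternatives from 0.112 to 0.944. Of 13 transcription factors of this transition, 2 were higher and 3 lower, with the same counts adjusted over the list alone (median -0.11, camera adjusted p = 0.81).

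A score per line, the mean of the mesenchymal list minus the mean of the epithelial list, was 4.84 ± 0.35 in Mes and 6.32 ± 0.65 in Epi lines. The difference of -1.48 had an exact two-sided permutation p of 0.0159, and 0.00794 is the smallest p that this design allows. The call ended without the filter on dim probes (-0.44, exact p = 0.111), and within slide 2 the difference was -0.50 (exact p = 0.333, with 3 arrays). Paired by replicate number, it had an exact p of 0.0625. Without Epi5 the difference was -0.91. The epithelial part differed by 1.12 (exact p = 0.0159), against a median over its genes of 0.73. Among its genes only F11r differed, at 12.53 in Mes and 8.98 in Epi lines. The mesenchymal part differed by -0.36 (exact p = 0.0635). Cdh1, removed by the filter, and the keratin list had lower means in Mes lines and entered neither part. Over the alternatives the exact p ranged from 0.00794 to 0.333, and the epithelial part rests on 5 genes.

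Few neuroendocrine genes passed the filter on dim probes. Of 30, 12 were above background on no array, 9 were measured, 1 was higher and 1 lower, or 0 and 1 adjusted over the list alone. Ddc, which makes dopamine and serotonin from their precursors, was off on all Mes arrays and at least 9.19-fold higher in Epi lines (adjusted p = 0.000535), a call that ended with a floor of 16 (adjusted p = 0.0737, the largest over the alternatives that keep all arrays and leave slides out of the model). Ncam1, a neural cell adhesion molecule, was higher in Mes lines by 0.87 (adjusted p = 0.0439), a call that ended without any one of Mes1, Mes2, Mes3, Mes5, Epi2, Epi3, Epi4 or Epi5 (adjusted p of up to 0.0997) and with 75th percentile scaling, normexp, no filter or a floor of 16 (up to 0.0986). Neurod1, Pou2f3 and Mycn, markers of other small cell lung cancer types, were not well above background on any array. The list median was 0.01 (camera adjusted p = 0.81, mean -0.29), and 0.12 with slide as a block (adjusted p = 0.844) and within slide 2 (adjusted p = 0.741). Without chromosomes 4, 9 and 10 it turned to -0.27 (adjusted p = 0.402), and adjusted p over alternatives ran from 0.402 to 0.977.

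Notch genes differed in both directions. Of 15 measured, 5 were higher and 5 lower, or 7 and 5 adjusted over the list alone. Notch3, a Notch receptor, was at least 12.4-fold higher in Mes lines (adjusted p = 0.000375) and above background on 1 of 5 Epi arrays. Jag2, a Notch ligand, was off on all Epi arrays and at least 6.22-fold higher in Mes lines (adjusted p = 0.000829). Notch2 was lower by -0.89 (SE 0.22, adjusted p = 0.0142), and Hes1, a Notch target, had an adjusted p of 0.523. Rest, the repressor of neuronal genes, was higher by 0.47 (adjusted p = 0.0357), a call that ended without any one of Mes1, Mes2, Mes3, Mes4, Epi1, Epi2, Epi3 or Epi4 (adjusted p of up to 0.0803) and with the replicate number as a block (0.106). The list did not pass (median 0.47, camera adjusted p = 0.605).

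Genes of the Wnt pathway differed in both directions. Of 24 measured, 3 were higher and 8 lower, or 4 and 8 adjusted over the list alone (median -0.49, camera adjusted p = 0.141). The median was -0.0038 with slide as a block and within slide 2, and the list passed without Epi2 (adjusted p = 0.039), with adjusted p over the alternatives from 0.039 to 0.944. Sfrp1, a secreted inhibitor of Wnt, was 0.89 ± 0.91 in Mes, where 1 of 5 arrays was above background, and 12.25 ± 0.63 in Epi lines, at least 941-fold higher in Epi lines (adjusted p = 1.62e-07). Wnt10a, a ligand, was at least 191-fold higher in Epi lines (adjusted p = 0.0011), with 1 of 5 Mes arrays above background, and Wnt9a differed by -2.96 (SE 0.52, adjusted p = 0.00322). Wnt5a, a ligand of the non-canonical branch, was higher by 4.89 (SE 0.67, adjusted p = 0.00106).

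Among receptor tyrosine kinases and secreted factors, more genes were called lower than higher, but neither list passed camera. Of 32 kinases and ligands, 2 were higher and 7 lower, with the same counts adjusted over the list alone (median -0.31, camera adjusted p = 0.0976). Efnb1, a ligand of Eph receptors, was at least 78.8-fold higher in Mes lines (adjusted p = 0.000704), with 4 of 5 Epi arrays above background. Fgfr2, a fibroblast growth factor receptor, was off on all Mes arrays and at least 44.0-fold higher in Epi lines (adjusted p = 0.000345). Igf1, insulin-like growth factor 1, was at least 45.2-fold higher in Epi lines (adjusted p = 0.00427), with 3 of 5 Mes arrays above background. Of 15 cytokines and chemokines, 0 were higher and 2 lower, with the same counts adjusted over the list alone (median -0.66, camera adjusted p = 0.204). Il33, an alarm cytokine, differed by -5.39 (SE 1.26, adjusted p = 0.0117). The cytokine list passed without Mes1 (median -1.53, adjusted p = 0.0166). With slide as a block (-2.99, adjusted p = 0.00768) and within slide 2 (adjusted p = 0.000116) the value rests on Epi2 alone, and on slides 1 and 3 only the median turned to 0.09, with adjusted p over alternatives from 0.000116 to 0.938.

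**Figure D2:**
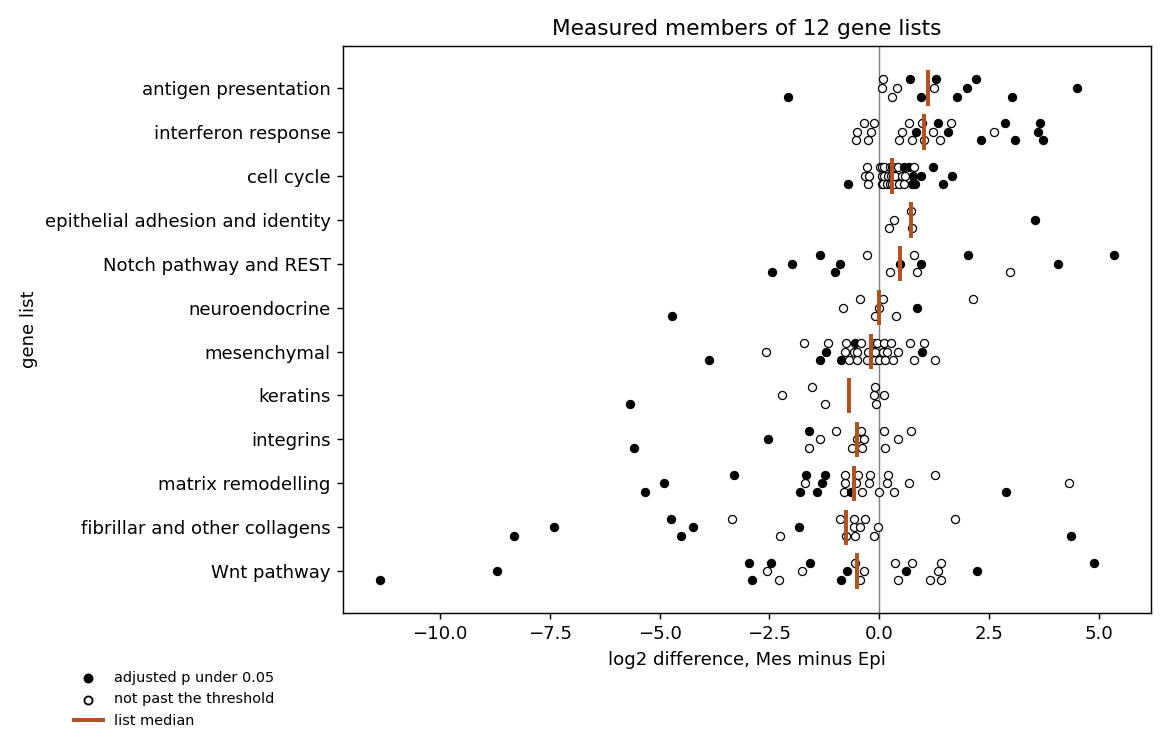
Log2 difference, Mes minus Epi (horizontal axis), of every measured member of 12 gene lists, with filled points for genes with an adjusted p under 0.05, open points for the others and an orange line at each list median. Antigen presentation has a median of 1.11 and the collagens -0.76, and the Wnt and Notch lists spread to both sides of 0.

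The remaining lists did not pass camera. In the TGF-beta pathway, 5 of 27 genes were higher and 1 lower, with the same counts adjusted over the list alone (median 0.10, camera adjusted p = 0.81). The median of this pathway turned to -0.10 without Mes5. Smad7, an inhibitor of this pathway, rose by 1.01 (SE 0.17, adjusted p = 0.00236), and Tgfbr1, its receptor, was lower by -1.08 (adjusted p = 0.00879). Of 29 targets and partners of YAP and TAZ, 3 were higher and 1 lower, or 2 and 1 adjusted over the list alone (median -0.19, camera adjusted p = 0.45), and Yap1 itself had an adjusted p of 0.801. In the MYC family 1 of 7 was higher and 1 lower, with the same counts adjusted over the list alone (median 0.18, camera adjusted p = 0.605), and Myc had an adjusted p of 0.333. Of 19 genes of the RB and p53 pathway, 1 was higher and 1 lower, with the same counts adjusted over the list alone (median -0.16, mean 0.02, camera adjusted p = 0.605). Sesn2, a stress-induced inhibitor of growth signalling, rose by 2.02 (SE 0.44, adjusted p = 0.00859).

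Among 23 immediate early and stress genes, 1 was higher and 3 lower, or 0 and 3 adjusted over the list alone (median 0.17, mean -0.27, camera downward with adjusted p = 0.864). Egr2, a transcription factor induced by growth signals, differed by -4.61 (SE 0.69, adjusted p = 0.00157), and Fos by -2.02 (SE 0.50, adjusted p = 0.0151). Of 26 glycolysis and hypoxia genes, 0 were higher and 5 lower, or 0 and 2 adjusted over the list alone (median -0.17, camera adjusted p = 0.204). Hk1, a hexokinase, differed by -0.86 (adjusted p = 0.0199), a call that ended without Epi3 (adjusted p = 0.0521) and with the replicate number as a block (0.0564). The glycolysis list passed without Mes1 (median -0.40, adjusted p = 0.0145), while its median was -0.06 without Mes4. With slide as a block (-0.69, adjusted p = 0.00875) and within slide 2 (adjusted p = 0.00178) the value rests on Epi2 alone, and on slides 1 and 3 only the median turned to 0.03, with adjusted p over alternatives from 0.00178 to 0.907. Of 19 cholesterol synthesis genes, 0 were higher and 1 lower, with the same counts adjusted over the list alone (median -0.22, camera adjusted p = 0.19). The list passed without Mes1 (median -0.47, adjusted p = 0.0204, over alternatives from 0.0204 to 0.716), while its median was -0.04 without Mes2. The lower one was Cyp51, a demethylase of this pathway, by -1.60 (SE 0.37, adjusted p = 0.0107).

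Markers of other cell types were examined as well. Of 5 measured tuft cell genes, 2 were lower, or 4 adjusted over the list alone (median -2.27, camera adjusted p = 0.0588), and the list passed without Mes5 (adjusted p = 0.0352), with the replicate block (0.0306) and on slides 1 and 3 only (0.0442), over alternatives from 0.0306 to 0.377. Dclk1, a kinase of tuft cells, differed by -2.48 (SE 0.61, adjusted p = 0.0148). Of 10 alveolar, club and basal genes of the lung, 1 was higher and 2 lower, with the same counts adjusted over the list alone (median 0.06, mean -0.61, camera downward with adjusted p = 0.658). The median of these lung genes turned to -0.05 without Epi4. Aqp5, a water channel of alveolar cells, differed by -7.29 (SE 0.79, adjusted p = 0.000397). Of 7 endothelial genes, 0 were higher and 2 lower, or 1 and 2 adjusted over the list alone (median 0.18, mean -0.74, camera downward with adjusted p = 0.378). This median turned to -0.77 without Epi1, -0.20 without Mes4, -0.12 with normexp, -0.27 with array weights and -0.73 without chromosomes 4, 9 and 10. Flt1, a receptor of vascular endothelial growth factor, differed by -3.31 (SE 0.58, adjusted p = 0.00298). Of 8 leukocyte genes, 1 was higher and 1 lower, with the same counts adjusted over the list alone (median -0.11, camera adjusted p = 0.605). The leukocyte median turned to 0.03 without Mes5. Csf1r, the receptor of a macrophage growth factor, differed by -2.21 (SE 0.34, adjusted p = 0.00173), and Cd68, a macrophage protein, by 1.26 (SE 0.23, adjusted p = 0.00371). The 2 measured genes of the erythroid and muscle list, Hbb-b1 and Ttn, had adjusted p of 0.563 and 0.109, also without a call adjusted over the list alone. Xist, expressed from an inactive X chromosome, was 14.19 ± 0.28 in Mes and 13.77 ± 0.32 in Epi lines (adjusted p = 0.125), while the Y-linked genes Ddx3y, Eif2s3y, Kdm5d, Usp9y and Uty were at background on all arrays, and 1 probe each of Zfy1 and Zfy2 was above it.

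Among genes measured on all 10 arrays whose groups do not overlap, the largest downward differences outside the lists were those of Ldhb, a subunit of lactate dehydrogenase, at -7.52 (SE 0.59, adjusted p = 6.04e-05), and of Tmem119 at -6.07 (SE 0.85, adjusted p = 0.00119). Cryab, a small heat shock protein, differed by -5.82 (SE 0.64, adjusted p = 0.000424), Pcp4l1 by -5.87 (SE 0.62, adjusted p = 0.000345), Slc1a3, a glutamate transporter, by -5.70 (SE 0.69, adjusted p = 0.00061), Slco2a1, a prostaglandin transporter, by -5.57 and Trpv4, a calcium channel, by -5.51. Upward, Plcg2, a phospholipase of immune receptor signalling, differed by 6.16 (SE 1.12, adjusted p = 0.00362) and Cdh15, a cadherin of muscle precursors, by 6.02 (SE 1.44, adjusted p = 0.0126). Tgif2, a transcriptional repressor, differed by 5.00, Chst10, a sulfotransferase, by 4.94, Tmod2, which caps actin filaments, by 4.19 and Dlgap3, a protein of synapses, by 4.10.

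Of the differing genes, 46 were off on all Epi arrays and 23 on all Mes arrays, where only a bound on the difference can be given. Robo1, a receptor of axon guidance, was at least 107.2-fold higher in Mes lines (adjusted p = 2.23e-08), Mageh1 at least 93.4-fold, Gsta4, a glutathione transferase, at least 47.7-fold and Nat8l, which makes N-acetylaspartate, at least 42.4-fold. Cobl, an actin nucleator, was at least 116.4-fold higher in Epi lines (adjusted p = 2.72e-06), Tox, a regulator of T cell development, at least 34.5-fold and Sema3a, a guidance signal for axons, at least 27.1-fold.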

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

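The slide test and both collagen I tests below were chosen only after the result was seen, while the counts of other splits were set before. A single line stood apart from the 4 others of its group, by the ratio of its gap to the group's range, for 14 of 238 pairs of gene and group and 4 of 56 pairs of list and group, and chance gives about 1 in 20. In Mes1, Cxcl10 was highest (ratio 0.764), as were Krt7 (0.728), Pfkl (0.778), the mean of the YAP and TAZ list (0.818) and that of the glycolysis list (0.75), while Gsta4 (0.751) and Mageh1 (0.714) were lowest, so 7 of the 18 fell on Mes1. In Epi1, Notch3 (0.975) and Shfl (0.791) were highest and Pdgfra (0.824) lowest. The integrin mean was lowest in Epi2 (0.815). Pcp4l1 was highest in Mes4 (0.784) and the Wnt mean in Mes5 (0.828). Robo1 in Epi4 (0.907) and Tox in Mes3 (0.847) stood apart at signals that were not above background.

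The number of genes that differed, 3752, was weighed against chance and against the slides. Of 100 splits of the 10 arrays, the real one included, 1 gave as many genes (highest other 567), 1 as many probes (6770 against 1033) and 1 as many genes at least 2-fold different (1749 against 301), the highest by genes being the 4 Epi arrays of slide 1 with Mes1. Chance therefore does not account for these counts, while for the 4 gene lists it cannot be excluded, since 54 of 100 splits gave as many and the highest gave 9. Of the genes tested on all arrays, 1893 differed on slides 1 and 3 alone, and of these 92.7% had the same sign within slide 2, against 71.6% of all tested genes. A difference between slides alone would give about as many opposite signs. Epi2 correlated at 0.959 to 0.969 with the Epi arrays of slide 1, but at 0.922 with Mes3 and 0.930 with Mes4 on its own slide. For Epi2, Mes3 and Mes4 the values thus followed the group rather than the slide. The Epi side on slide 2 is Epi2 alone, so slides may still be a cause elsewhere and a difference between the lines is a hypothesis.

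The genes of collagen I, Col1a1 and Col1a2, were higher in lines labelled Epi. The 7 members of the mesenchymal list with a low baseline in Mes lines lay at least 7.81 (log2, 225-fold) below Col1a2 in Epi lines. Their median gap was 15.2 (log2), while fibroblasts were predicted to give a median within 10-fold. Signal levels of different genes are not comparable, however. Spock1 (0.90), Thy1 (1.70) and Lum (2.45) were above background on at most 1 Epi array, so their gaps largely reflect the floor. But 2 probes of Col1a2 itself lay 512-fold apart on the same arrays, more than the smallest gap, of Fbln1. Neither the smallest gap nor the median gap can therefore decide on fibroblasts among the Epi cells. The limit first set, 10-fold, would have excluded them and was replaced by the probe gap after the value was seen. Dcn (4 Epi and 1 Mes arrays above background), Mmp2 (3 and 2) and Lum (1 and 0) lean to the Epi lines and Fap (2 and 4) to the Mes lines. These counts do not decide on fibroblasts either. The labels describe each line as grown from a single cell, which would remove fibroblasts mixed in from the tumour. Of 54 epithelial and keratin genes, 8 were above background on more Mes arrays and 15 on more Epi arrays (exact two-sided binomial p = 0.21), which does not decide on an exchange of the group labels, with Krt7 (8.07 against 2.40), Cdh1, Krt8, Krt19 and Krt80 going with the labels and Spint1, Esrp2 and F11r against them. Cdh1 and Krt8 did not overlap between the groups. F11r and Esrp2 did, as did the brighter of 2 Spint1 probes. The other Spint1 probe did not, but only 2 Mes and 0 Epi arrays were above background on it. Keratin list means per line did not overlap (3.23 to 4.34 in Mes, 4.47 to 5.45 in Epi lines). Epithelial adhesion list means were higher in Mes lines and overlapped (6.4 to 7.1 against 5.2 to 6.6). An exchange of labels may still be a cause, and a difference between the lines stays open as untested.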

How the results depend on the processing

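The settings without chromosomes 4, 9 and 10 and without slide 2 were chosen only after the result was seen. Of the 103 named genes that differed, 75 kept their call under those alternatives set in advance that keep all arrays, have no fixed slide term and were run on the gene, and 77 kept it without any one array. Only 71 of the 103 could be tested with probes above background on all 10 arrays, and the mean over probes was run for counts alone. With normexp background correction, whose offset shrinks folds by construction, 771 genes differed at least 2-fold against 1749, and the score difference was -0.441 (exact p = 0.111) without the filter on dim probes; the cause was not tested. With slide as a fixed block, 179 probes, 97 genes and 97 genes at least 2-fold differed, and 90 of the 103 named genes lost their call. Within slide 2 alone limma called 0 probes, 0 genes and 0 genes at least 2-fold, with 2290 genes at an unadjusted p under 0.05, and the score difference was -0.4985 (exact p = 0.333). Both contrasts rest on the 3 arrays of slide 2, which by construction leaves less precision. They also turned E2f2 to -0.04588 and Mxd4 to 0.01568; the cause was not tested. With slide as a random block 4227 genes differed, and the correlation of arrays on a slide was -0.0434. With an estimated correlation 0 lists passed, and fry, a test of another question, called 14 lists, the epithelial list among them (median 0.7333, adjusted p = 0.00876). Without chromosomes 4, 9 and 10, 4257 probes and 2388 genes differed, of fewer tested. On slides 1 and 3 only, 3421 probes, 1937 genes and 7 lists differed, with fewer arrays.

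The replicate numbers did not pair the arrays: same-numbered arrays had residual correlations of 0.014 to 0.0434 and 1 of 10 arrays correlated best with its own number. With the replicate block 2949 genes and 7 lists differed, and the score difference of -1.475 had an exact p of 0.0625, the smallest that 5 pairs allow. Leaving out single arrays gave 4822 to 7481 probes, 2668 (without Epi3) to 4132 genes, 1441 to 1979 genes at least 2-fold and 3 (without Mes4, Epi4 or Epi5) to 9 (without Mes1) lists. The score difference ran from -1.724 to -0.912 (without Epi5), the epithelial median from 0.2424 (without Epi5) to 0.882 (without Mes5), the mesenchymal median from -0.3064 (without Epi2) to -0.07045 (without Mes1) and the neuroendocrine median from -0.08117 (without Mes2) to 0.09694 (without Epi5); the cause was not tested.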

Other observations

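The tests by symbol family, by chromosome and of neighbouring genes were all chosen only after the result was seen. Of 644 tests on 322 families of gene symbols, 8 passed by Fisher's exact test with adjustment. This test counts the genes of a family as independent, which genes of 1 cluster need not be. Its p-values therefore do not measure the spread between lines and may be far too small. All 13 measured Pcdhb genes, a cluster on chromosome 18 of cadherins that give neurons their surface identity, were lower in Mes lines (median -2.70, or -2.42 with 2 genes at their bounds, adjusted p = 1.74e-09). Pcdhb17 was 7.47 ± 0.41 in Mes and 10.29 ± 0.59 in Epi lines. Of 11 annexins, which bind membranes with calcium, 9 were lower (median -0.84, adjusted p = 9.15e-05), led by Anxa8 at -7.14 (SE 1.38, adjusted p = 0.0049). Of 7 Ifitm genes, interferon-induced membrane proteins that block virus entry, 5 were lower (median -1.71, adjusted p = 0.0485), opposite to the interferon list, with Ifitm3 at -2.25 (SE 0.60, adjusted p = 0.0201).

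The families Cep (centrosomal proteins) and Rad (mostly DNA repair) held a larger share of genes higher in Mes lines than all other genes. Of 37 Cep genes, 17 were higher and 2 lower (median 0.64, adjusted p = 0.00148), among them Cep57 at 1.26 (SE 0.18, adjusted p = 0.0012). Of 18 Rad genes, 11 were higher and 0 lower (median 0.59, adjusted p = 0.00148). Cep57 and some other Cep genes lie on chromosome 9. The medians of these 5 families kept their sign under every scaling alternative and within slide 2. Within slide 2 they were -1.41 for Pcdhb, -0.766 for annexins, -2.23 for Ifitm, 0.3 for Cep and 0.253 for Rad, and with normexp -1.02, -0.704, -0.893, 0.309 and 0.417. Single members were not refitted without single arrays, and probes of such similar genes were not checked for shared signal. Of 83 Ccdc genes, 26 were higher (adjusted p = 0.0174), fewer Zfp genes were lower than elsewhere (19 of 311, adjusted p = 0.0113), and 0 of 105 olfactory receptors were higher (adjusted p = 1.81e-05).

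Genes on chromosome 9, the largest shift of the 20 chromosomes and picked for that, had a median 0.682 above that of all genes, with 435 higher and 20 lower in Mes lines, and every Mes line lay above and every Epi line below the mean of all lines (exact permutation p = 0.00794, the smallest possible, adjusted p = 0.0265). Quantile normalization does not account for it, with 0.669 after 75th percentile scaling. On slide 2, Mes3 lay at 0.309, Mes4 at 0.367 and Epi2 at -0.396. The Mes arrays of slide 3 lay at 0.29 to 0.321 and the Epi arrays of slide 1 at -0.362 to -0.256. These values followed the group rather than the slide. The 0.724 within slide 2 rests on Epi2 alone, however, so slides are not excluded. Of its 748 genes 83.8% were higher, against 50.2% elsewhere, which a chromosome picked for its median already implies and which is no test of a few strong genes. The lowest of 3 equal parts of the chromosome was at 0.652, which is consistent with a difference in the number of copies of the chromosome, a hypothesis, since DNA copy number was not analysed here. Chromosomes 4 (0.52, and 0.215 within slide 2, with Epi2 at 0.067) and 10 (-0.491, and -0.646 within slide 2, with Mes1 at 0.0828 and Epi1 at -0.0458) shifted less evenly over lines, and 7 of the 20 chromosomes passed the adjusted exact test.

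Of 69 differing genes off in 1 group, 2 pairs were neighbours among placed genes, Ddc with Cobl on chromosome 11, off in Mes, and D230034L24Rik with Robo1 on chromosome 16, off in Epi, against a mean of 0.184 in 10000 random placements (permutation p = 0.0148). Without RIKEN-named transcripts 1 pair was left (permutation p = 0.153), so the result rests on the Robo1 pair and tells nothing on loss or silencing of stretches of DNA.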
